A study of Homo sapiens with 36 samples.

How the data were processed

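Gene expression was read from 36 Illumina expression BeadChip arrays of cells labelled MCF-10A in 12 groups of 3 labelled biological replicates, and all p-values come from these replicates. The deposited signal file gives intensity per probe, which the authors neither normalized nor background subtracted, per its name and its values. Beside each signal stands a detection p-value that, per the file headers, belongs to the same probe and array. It moves in steps that correspond to 770 negative control bead types. The deposited series values are on the log2 scale, and the authors' method is not given in the sources used here. Quantile normalization of the log2 signals gave the same values to within 0.0013, and every deposited column had a median of 6.94. The scanner, the export software and the slide of each array were not given in the sources used here.

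Samples were joined to columns by the labels, with 72 columns listed and 0 without a sample. Each array was checked against the deposited values, and for 36 of 36 the best matching column was its own. No 2 arrays were identical (highest correlation 0.996). Replicate numbers did not pair the samples: residuals of arrays with the same number in different groups had a mean correlation of -0.000629, against 0.000385 for other numbers. Background signal lay between 93.2 and 126.5 intensity units and between 33.5% and 38.3% of probes were above background.

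Signals were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (offset 16, negative controls inferred from the detection p-values). Probes were kept when the detection p was under 0.01 on all 3 arrays of at least 1 group. Of 47231 probes, 30113 had 1 gene, 8 had several and 17110 had no gene listed. Of the 18905 probes detected in a group, 4033 had no single gene name and were left out. The probe with the highest mean stood for each gene, which left 11048 genes. Gene names were checked against the RefSeq gene table of GRCh38.p14, and 0 symbols changed. Computation used R 4.3.3, the data.table package (1.17.8) and, for the figures, Python 3.11.15 with matplotlib 3.10.9.

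A linear model with 12 group means was fitted to all 36 arrays with limma, so that the groups shared the estimate of the spread. Moderated t tests were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Each of 10 hairpin lines was compared with shControl, and a gene was called for a target when both hairpins passed with the same sign. Further comparisons were shControl against wild type, genes called in all 10 lines, each line against the 8 lines of the other 4 targets, and the 2 hairpins of a target against each other. The 27 gene lists were tested with camera, with the correlation between genes estimated from the data, on the mean of the 2 hairpin contrasts of each target and on shControl against wild type. These list tests were adjusted together over the 6 contrasts. A member of a list was counted as rising or falling when both hairpins passed.

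The comparisons, the lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were the target genes, then the 6 largest changes in each direction that both hairpins shared. These had to be above background on all arrays compared, with all hairpin arrays on one side of all shControl arrays. To them were added up to 2 genes above background on one side and 3 genes in each direction that set a target apart. List members called by both hairpins were also added. Up to 3 came from a called list, and up to 2 from other lists with at least 5 such members. The rule also took 8 genes in each direction for shControl against wild type and 10 for the comparison of all lines. Genes below background in one group were given no fitted fold: a lower bound was computed from the lowest detected signal of each array, or detection counts were given. GSTM1, GSTT1 and the other genes reported as present or absent across the 8 lines of 4 targets fell outside this rule and were chosen after their values were seen. MTAP, CDKN2A and CDKN2B also fell outside it: they were looked up for a known deletion, after the arrays had been seen to split by line. The rule set which genes could be named, and not all of them are printed. A gene that it named in the CHEK1 comparison is not reported here. In the comparison without the sh53BP1 lines, examples were taken from those with the largest change in the weaker hairpin.

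Alternatives were the deposited log2 values, no background correction (signals floored at 1), no filter on dim probes, the replicate number as a block, and each library left out in turn. Wild type replaced shControl, 1 hairpin was set against shControl and the other against wild type, only the compared groups were fitted, all probes were counted, and the list test was run with a preset correlation of 0.01. A comparison without the sh53BP1 lines was added after the data were examined, as was wild type as the control for the target mRNA. The slide as a block was not run, because no slides were given.

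The call for both hairpins was tested on simulated data with 200 changed genes among 11048, at the group sizes and spread of the ATM comparison. It recovered 16% of genes changed 1.25-fold, 64% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 1 false call. A list shifted by 0.3 on the log2 scale was called, with 0 other lists called. Most simulated changes of 1.25-fold were therefore missed.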

Results

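Messenger RNA was measured on 36 Illumina BeadChip arrays of cells labelled MCF-10A, the name of a non-transformed human mammary epithelial cell line. The arrays fall into 12 groups of 3 biological replicates: wild type (mock), shControl (a scrambled hairpin), and 10 lines that stably carried a lentiviral short hairpin. The hairpins were directed against ATM (shATM-1, shATM-3), ATR (shATR-3, shATR-4), CHEK1 (shCHK1-3, shCHK1-4), CHEK2 (shCHK2-1, shCHK2-2) and TP53BP1 (sh53BP1-1, sh53BP1-2). These genes encode kinases of the DNA damage signal and, for TP53BP1, the adaptor protein 53BP1. Per the labels, 200000 cells were seeded on a 10 cm plate and harvested after 48 hours. Each array carried 47231 probes, with a mean signal between 460 and 677 intensity units and between 33.5% and 38.3% of probes above background. The lowest correlation between replicates of a group was 0.984 (shCHK1-3). The median SD of a gene within a group lay between 0.10 and 0.19 on the log2 scale.

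The target mRNA of each hairpin was read first. TP53BP1 mRNA (probe ILMN_1664440) fell by 2.64 ± 0.145 (log2, SE, n = 3 arrays per group) in sh53BP1-1 and by 2.33 in sh53BP1-2, to 15.99% and 19.8% of shControl (adjusted p 1.06e-15 and 2.4e-14). ATM mRNA (ILMN_1779214) fell by 0.90 ± 0.156 in shATM-1 and by 1.03 in shATM-3, to 53.8% and 48.9% of shControl (adjusted p 9.93e-06 and 1.36e-06). A second ATM probe (ILMN_2370825) read -1.70 ± 0.162 in shATM-1 and -1.26 in shATM-3, and it was also lower than in shControl in shATR-3 (-0.75), shCHK1-3 (-0.80), shCHK2-2 (-0.83), sh53BP1-1 (-0.55) and sh53BP1-2 (-0.81). CHEK2 mRNA (ILMN_2395240) fell by 0.99 ± 0.193 in shCHK2-1 (50.2% of shControl, adjusted p 4.84e-05), whereas shCHK2-2 stood at 93.2% of shControl (log2 -0.10 ± 0.193, adjusted p 0.652). A second CHEK2 probe (ILMN_2395236) read -1.78 ± 0.145 in shCHK2-1 and -0.60 in shCHK2-2 (adjusted p 1.85e-11 and 0.00141). With the deposited log2 values, which hold background, the falls were smaller by over 1.5 times for TP53BP1 (-1.39 and -1.29) and for CHEK2 in shCHK2-1 (-0.47). The difference between these lines at the first CHEK2 probe was -0.89 ± 0.193 (adjusted p 0.000359). ATR mRNA could not be read, since its 3 probes were not above background on any shATR or shControl array.

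CHEK1 mRNA (ILMN_1664630) fell by 0.25 ± 0.095 in shCHK1-3 and by 0.27 in shCHK1-4, to 84.0% and 82.9% of shControl (n = 3 arrays per group, adjusted p 0.0204 and 0.0146). It was also lower in shControl (mean log2 signal 8.74) than in wild type (9.48), and it was higher than in shControl in each of the 8 lines directed against other genes. These differences ran from 0.81 (shATM-3) to 1.35 (shATR-3). With wild type as the control, also chosen after the data were examined, CHEK1 mRNA was -0.996 in shCHK1-3 and -1.014 in shCHK1-4, ATM mRNA -0.53 in shATM-1 and -0.67 in shATM-3, and CHEK2 mRNA in shCHK2-2 -0.27 (adjusted p 0.216 for the last). Against the 6 lines of ATM, ATR and CHEK2, a comparator chosen after the data were examined, CHEK1 mRNA was 38.8% in shCHK1-3 and 38.3% in shCHK1-4 (log2 -1.37 and -1.39 ± 0.072). Against the matching 6 lines, ATM mRNA was 61.2% and 55.6%, and CHEK2 mRNA was 34.2% in shCHK2-1 and 63.5% in shCHK2-2 (adjusted p 0.000818 for the last). The CHEK1 calls against shControl ended without shControl replicate 3 (-0.17 in shCHK1-3, -0.19 in shCHK1-4), without shCHK1-3 replicate 1 (-0.21) or 3 (-0.22), and without shCHK1-4 replicate 2 (-0.24).

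**Figure D1:**
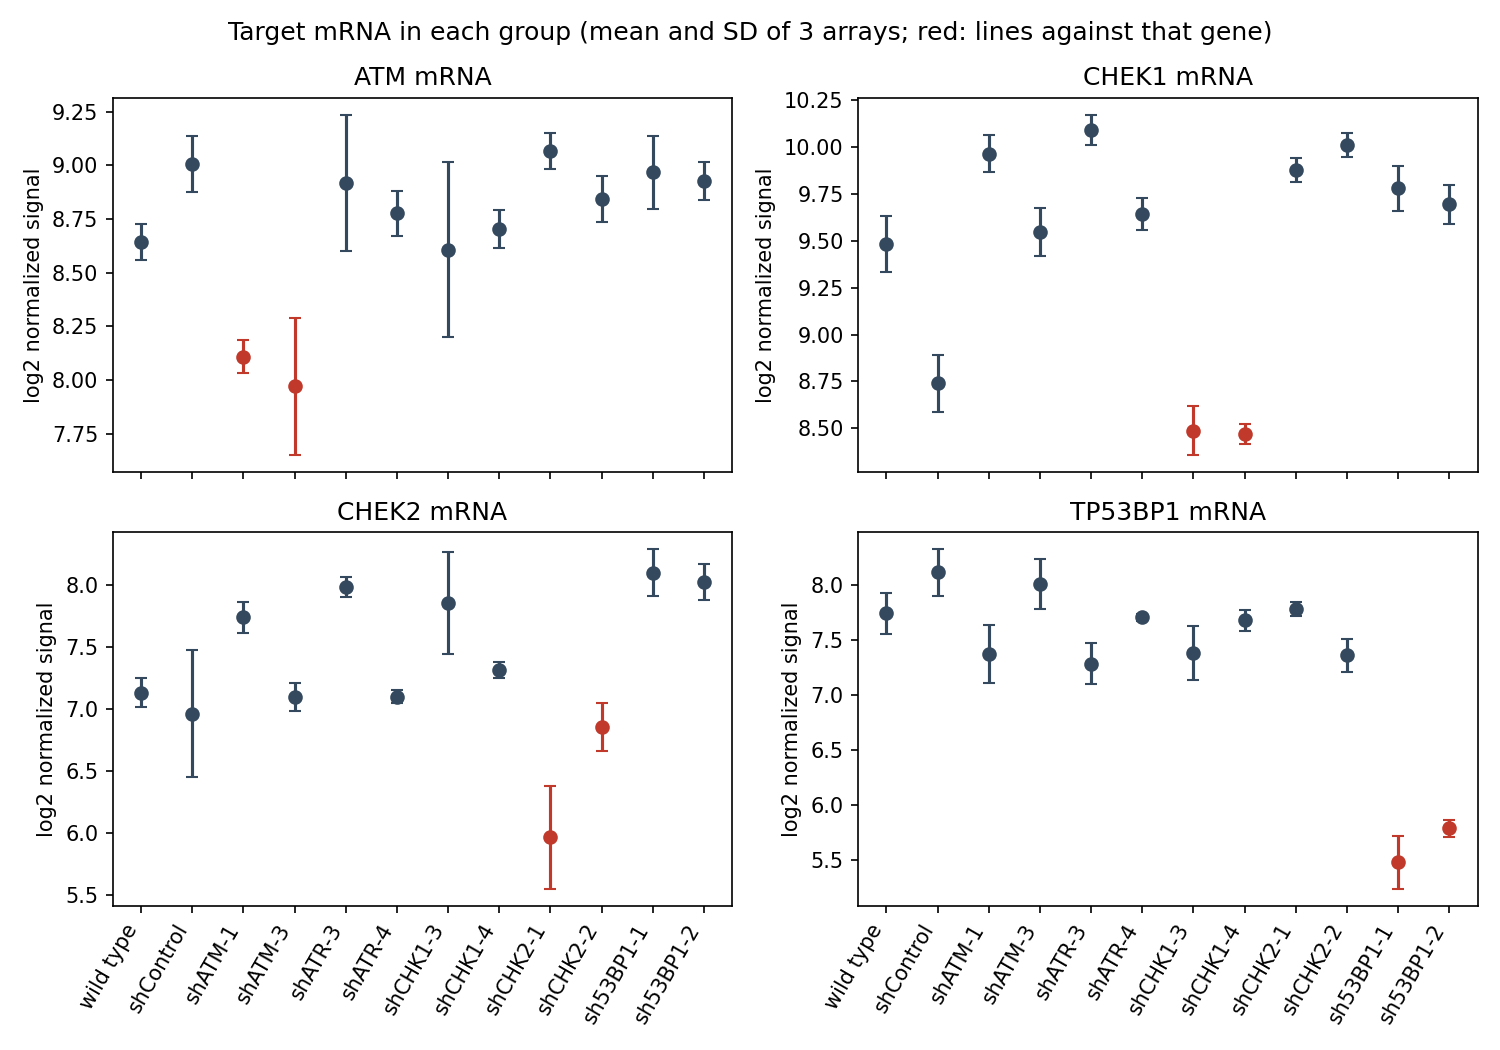
Mean log2 normalized signal (vertical axis) of ATM, CHEK1, CHEK2 and TP53BP1 in each of the 12 groups (horizontal axis), with the SD of 3 arrays as bars and the lines directed against each gene in red. The shControl mean of CHEK1 (8.74) lies below the wild type mean (9.48).

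The 8 lines of ATM, ATR, CHEK1 and CHEK2 stood apart from the other 4 groups in genes that were present or absent. MTAP (methylthioadenosine phosphorylase), CDKN2A and CDKN2B (inhibitors of the kinases CDK4 and CDK6) and the cyclin gene CCND2 were above background on all 24 arrays of the 8 lines and on none of the 12 arrays of wild type, shControl and sh53BP1. The log2 signal of MTAP on single arrays ran from 8.98 to 10.43 in the 8 lines and from 4.50 to 5.02 in the others. DKK3, FEZ1, GJA1, FBN2 and GSTT1 gave the same split. MSLN (mesothelin), CYBA, PLAAT3, COX7A1, RARRES1, EPDR1 and ANPEP were above background on all 12 arrays of the other groups and on none of the 24. In all, 88 genes of 11048 were detected on every array of the 8 lines and on no other array, and 98 gave the reverse. These genes were described and not tested, and apart from MTAP, CDKN2A and CDKN2B their names were chosen after the values were seen.

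The first principal component held 60.4% of the variance and placed the 8 lines between 27.5 and 34.9, sh53BP1 between -64.0 and -62.6, shControl between -64.6 and -64.0, and wild type between -69.4 and -68.3. The second held 17.2% and split the hairpins of each of the 4 kinases. On it, shATM-1, shATR-3, shCHK1-3 and shCHK2-2 lay between 15.6 and 25.2, and shATM-3, shATR-4, shCHK1-4 and shCHK2-1 between -28.1 and -13.3. The line with the most similar profile belonged to the same target for 2 of 10 lines, both sh53BP1 (r = 0.930 across genes, which are not independent replicates). The profile of shATR-3, as an example, was closest to shCHK2-2 (r = 0.872) and had r = 0.122 with shATR-4.

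**Figure D2:**
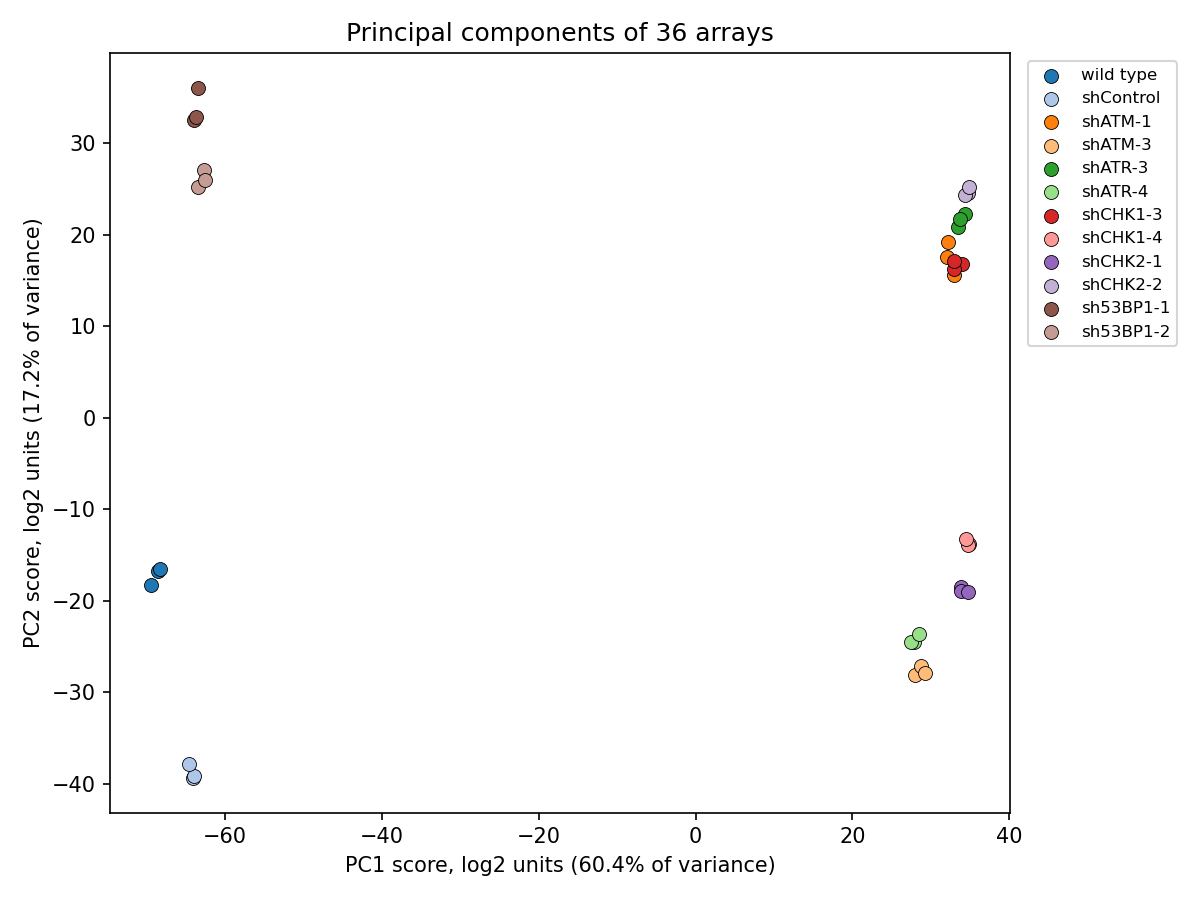
Scores of the 36 arrays on the first component (horizontal axis, 60.4% of the variance) and the second (vertical axis, 17.2%), in log2 units, with 1 point per array and 1 colour per group. The 24 arrays of the ATM, ATR, CHEK1 and CHEK2 lines lie between 27.5 and 34.9 on the first component.

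**Figure D3:**
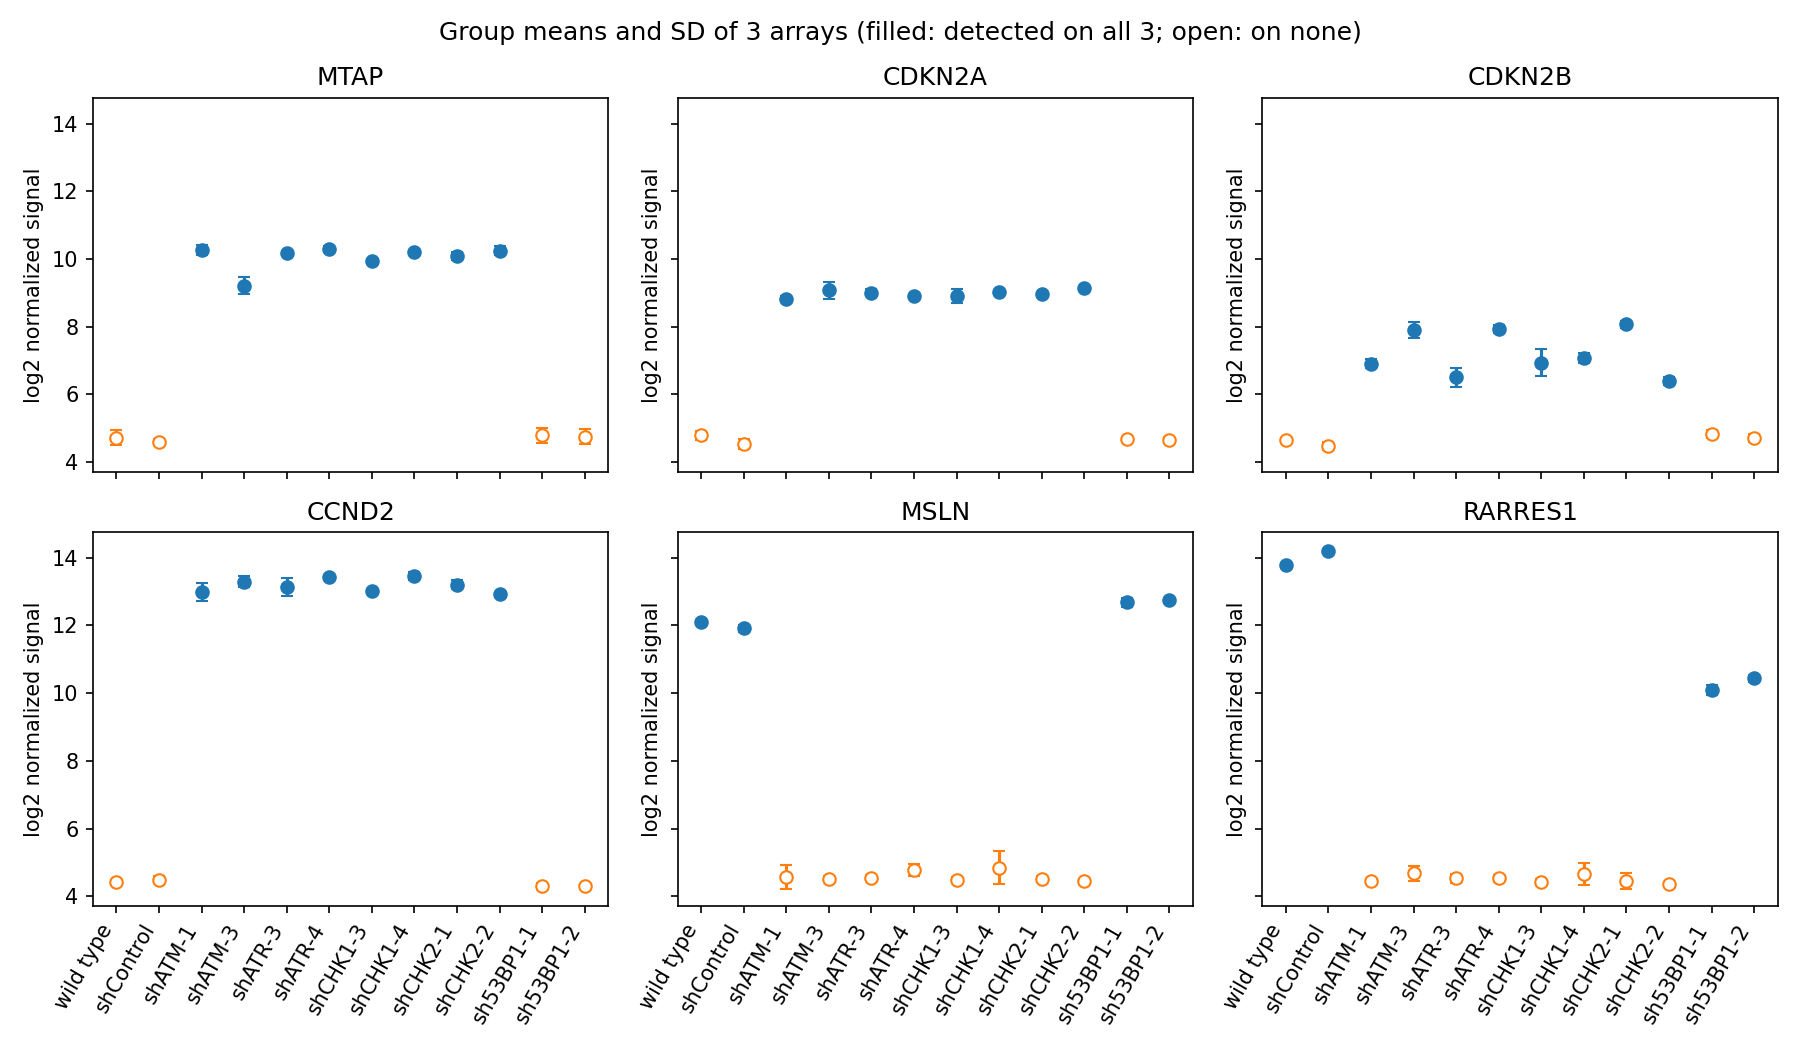
Mean log2 normalized signal (vertical axis, SD of 3 arrays as bars) of MTAP, CDKN2A, CDKN2B, CCND2, MSLN and RARRES1 in each group (horizontal axis), with filled points where all 3 arrays were above background and open points where none was. MTAP, CDKN2A, CDKN2B and CCND2 were above background on 24 of the 24 arrays of the ATM, ATR, CHEK1 and CHEK2 lines.

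The scrambled hairpin was compared with wild type. Transduction, selection and any other difference between these groups cannot be told apart here, and the p-values measure the spread between replicates within groups. Inflammatory genes were higher in shControl (n = 3 against 3 arrays): PTGS2, the cyclooxygenase of inflammation, 37.9-fold (log2 5.24 ± 0.127, adjusted p 1.66e-23), the chemokine CXCL1 28.5-fold and the cytokine IL6 19.99-fold. S100A7, PI3 and S100A8 were 125-fold, 39.7-fold and 37.6-fold higher, and the aldehyde and ketone metabolising enzymes AKR1B10 and ALDH3A1 19.1-fold and 17.3-fold higher. Lower in shControl were the kallikrein proteases KLK7 (23.9-fold) and KLK6 (5.56-fold), PADI4 (6.89-fold), PLAC8 (6.37-fold), CTH, an enzyme of cysteine synthesis (5.79-fold), the gelatinase MMP9 (5.61-fold), EPSTI1 (4.73-fold) and PKIB (4.57-fold).

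Of the gene lists fixed before the data were examined, the cell division lists fell in shControl. In the G2/M list 30 of 32 measured genes fell and none rose (30 adjusted over the list alone; list test adjusted p 4.83e-05), among them TPX2 (-1.06 ± 0.136) and CENPF (-0.92). In the G1/S list 23 of 29 fell (25 adjusted over the list alone; adjusted p 1.7e-06), with TK1 at -0.97 and MCM5 at -0.91. Homologous recombination genes fell in 14 of 24 cases (17 adjusted over the list alone; adjusted p 0.000772; BARD1 -0.80, EXO1 -0.78). Fanconi anaemia genes fell in 6 of 12 (8 adjusted over the list alone; adjusted p 0.00938; FANCI -0.75). Inflammatory and secretory factors rose in 17 of 21 cases and fell in 1 (18 and 1 adjusted over the list alone; adjusted p 6.27e-07). Mesenchymal and fibroblast markers rose in 10 of 16 (10 adjusted over the list alone; adjusted p 2.57e-05), with the intermediate filament gene VIM 4.89-fold higher. Hypoxia and glycolysis genes rose in 13 of 25 (13 adjusted over the list alone; adjusted p 0.000696; LOX 3.51-fold). TGF-beta targets rose in 11 and fell in 1 of 16 (12 and 1 adjusted over the list alone; adjusted p 0.019; ID3 2.66-fold higher, THBS1 2.69-fold lower). NRF2 targets rose in 12 of 14 (12 adjusted over the list alone; adjusted p 0.000696; GCLC 3.49-fold). In all, 3375 of 11048 genes differed between shControl and wild type, 1606 higher and 1769 lower in shControl.

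Among genes above background on all arrays compared, those higher than shControl in both ATM lines were led by FST. This gene of the activin-binding protein follistatin was 48.96-fold higher in shATM-1 and 136-fold higher in shATM-3 (log2 5.61 and 7.09 ± 0.086, n = 3 arrays per group, adjusted p 1.41e-29 and 3.36e-32). LPAR1, a receptor of lysophosphatidic acid, was 18.8-fold and 15.7-fold higher, the keratin KRT6C 14.4-fold and 22.7-fold, and the hyaluronan synthase HAS3 12.3-fold and 19.5-fold. The neurotrophic factor ARTN was 11.8-fold and 18.95-fold higher, and the cytokine IL1B 11.1-fold and 21.5-fold. The mucin MUC1 was 69.8-fold and 64.7-fold lower, the calcium-binding proteins S100A7 182-fold and 49.2-fold and S100A4 107-fold and 37.2-fold. Also lower were the protease inhibitor SERPINA3 57.4-fold and 21.6-fold, DBNDD1 29.4-fold and 24.2-fold, and TENT5A 29.6-fold and 18.8-fold. As the naming rule required, all 6 hairpin arrays lay on one side of all 3 shControl arrays for each of these 12 genes. Over the named genes of all comparisons, log2 changes with the deposited values were a median of 0.767 times those given here, and 134 of 470 were smaller by over 1.5 times. RARRES1 was at least 460-fold lower, being below background in the lines, and CCND2 at least 209-fold higher, being below background in shControl. MTAP and CDKN2A, absent from shControl, were above background on all 6 arrays of these lines. The changes in this paragraph were not separated from whatever set the lines of all the kinases apart from shControl in these genes.

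All 14 measured NRF2 targets, genes of the oxidative stress defence, fell in both ATM lines (14 adjusted over the list alone; list test adjusted p 0.000696), with AKR1C2 at -7.36 and -3.50 and AKR1C3 at -6.47 and -3.70. In shControl 12 of these 14 were higher than in wild type. Of 24 keratinocyte differentiation genes 15 fell (15 adjusted over the list alone; adjusted p 0.0394), among them S100P (-6.90 and -4.13) and the kallikrein KLK5 (-5.54 and -2.17). Of 14 luminal epithelial markers 8 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p 0.019), with ELF3 at -3.15 and -2.58 and AGR2 at -3.75 and -1.44. Hypoxia and glycolysis genes fell in 12 and rose in 3 of 25 cases (13 and 3 adjusted over the list alone; adjusted p 0.0397), with VEGFA at -1.67 and -1.20. G2/M genes rose in 18 of 32 (18 adjusted over the list alone; adjusted p 0.0243), with TPX2, a spindle assembly factor, at 1.87 and 1.60 and the mitotic kinase AURKA at 1.12 and 1.18. G1/S genes rose in 10 and fell in 1 of 29 (10 and 1 adjusted over the list alone; adjusted p 0.00931), with the phosphatase CDC25A at 1.14 and 0.98 and the cyclin CCNE1 at -0.80 and -0.85. Interferon response genes rose in 5 and fell in 2 of 30 (5 and 2 adjusted over the list alone; adjusted p 0.0456), but the call rested on shATM-3: the mean change of the list was -0.19 in shATM-1 and 1.36 in shATM-3 (medians -0.12 and 1.20). ISG15 was 0.45 ± 0.156 in shATM-1 and 3.91 in shATM-3, and its call for both hairpins was lost without shControl replicate 1 (mean of the hairpins 2.13) or 2 (2.04). With wild type as the control the NRF2 (adjusted p 0.0323) and luminal lists (adjusted p 0.00378) were called. Not called were G1/S (0.268), G2/M (0.735), hypoxia (0.86), keratinocyte (0.229) and interferon genes (0.135), and the G1/S and G2/M medians turned to -0.14 and -0.062. In both ATM lines 4998 genes differed from shControl, 2471 higher and 2527 lower. Of these, 3979 (79.6%) were called with the same sign for ATR, CHEK1 and CHEK2 too. Those changes were not particular to ATM, and the 8 lines of these targets also differed from shControl in MTAP and CDKN2A.

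In the ATR lines FST was 45.5-fold and 161-fold higher in shATR-3 and shATR-4 (log2 5.51 and 7.33 ± 0.086, n = 3 arrays per group), the cytokine IL24 13.1-fold and 26.6-fold, and LPAR1 16.6-fold and 18.98-fold. KRT6C was 14.1-fold and 25.8-fold higher, ARTN 12.1-fold and 21.5-fold, and IL1B 11.3-fold and 26.5-fold (adjusted p 5.83e-20 and 3.11e-23 for IL1B). S100A4 was 110-fold and 45.6-fold lower, MUC1 91.6-fold and 44.4-fold, the cytochrome CYP1B1 63.6-fold and 21.6-fold. Lower too were the drug efflux transporter ABCC3 35.9-fold and 17.9-fold, the reductase AKR1C4 105-fold and 17.4-fold, and DBNDD1 38.98-fold and 18.7-fold. By the naming rule, all 6 hairpin arrays lay on one side of the 3 shControl arrays for each of these 12 genes. RARRES1 was at least 469-fold lower and CCND2 at least 232-fold higher, and MTAP was above background on all 6 arrays and on no shControl array. An effect of the ATR hairpins was not separated from whatever set all the kinase lines apart from shControl in MTAP, and ATR mRNA could not be read.

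G2/M genes rose in 22 of 32 cases in both ATR lines (22 adjusted over the list alone; adjusted p 0.00796; CDC20, an activator of the anaphase ubiquitin ligase, 1.35 and 1.19). G1/S genes rose in 15 and fell in 1 of 29 (15 and 1 adjusted over the list alone; adjusted p 0.00173; the replication factor CDC45 1.23 and 0.73). Homologous recombination genes rose in 12 and fell in 1 of 24 (12 and 1 adjusted over the list alone; adjusted p 0.0284), with PSMC3IP at 1.72 and 0.66 and the nuclease EXO1 at 1.11 and 0.85. Fanconi anaemia genes rose in 7 of 12 (7 adjusted over the list alone; adjusted p 0.0456), with FANCE at 1.48 and 0.86 and FANCG at 1.12 and 0.67. Luminal markers fell in 7 and rose in 2 of 14 (7 and 2 adjusted over the list alone; adjusted p 0.0394; AGR2 -3.91 and -1.32). In the same lines hypoxia and glycolysis genes fell in 13 and rose in 3 of 25 (13 and 3 adjusted over the list alone; adjusted p 0.0343; VEGFA -1.86 and -0.96) and NRF2 targets fell in 11 of 14 (13 adjusted over the list alone; adjusted p 0.00102; AKR1C3 -6.50 and -4.07). Against wild type the luminal list was called (adjusted p 0.00909) and the other 6 were not: G1/S 0.623, G2/M 0.771, homologous recombination 0.795, Fanconi 0.523, hypoxia 0.948 and NRF2 0.0637. The G1/S median turned to -0.077. In both ATR lines 5266 genes differed from shControl, 2582 higher and 2684 lower, with the 3979 genes shared by ATM, ATR, CHEK1 and CHEK2 among them.

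In both lines directed against CHEK1, FST was 70.2-fold and 171-fold higher than in shControl (log2 6.13 and 7.42 ± 0.086, n = 3 arrays per group), LPAR1 18.04-fold and 20.4-fold, and KRT6C 19.9-fold and 15.5-fold. Higher too were ARTN 14.8-fold and 29.4-fold, HAS3 11.8-fold and 23.1-fold, and the antiviral membrane protein IFITM3 12.8-fold and 13.2-fold (adjusted p 6.34e-20 and 4.82e-20 for IFITM3). S100A7 was 142.1-fold and 139.8-fold lower, S100A4 130-fold and 79.2-fold, and S100P 107-fold and 72.99-fold. Lower too were SERPINA3 60.8-fold and 69.5-fold, COXFA4L3 30.03-fold and 81.2-fold, and DBNDD1 37.4-fold and 30.7-fold. RARRES1 was at least 466-fold lower and CCND2 at least 215-fold higher, and CDKN2A was above background on all 6 arrays and on no shControl array. Here too, an effect of the hairpins was not separated from whatever set all the kinase lines apart from shControl in CDKN2A. For the 12 genes above background on all arrays, the 6 hairpin arrays lay on one side of the 3 shControl arrays, as the naming rule required.

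Genes of cell division rose against shControl in the CHEK1 lines: 25 of 32 G2/M genes (25 adjusted over the list alone; adjusted p 0.00318), with KIF2C at 1.33 and 1.41. Of 29 G1/S genes 21 rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p 0.000957), with CDC45 at 1.18 and 1.14. Homologous recombination genes rose in 14 of 24 cases (14 adjusted over the list alone; adjusted p 0.0218). Keratinocyte genes fell in 15 and rose in 1 of 24 (16 and 1 adjusted over the list alone; adjusted p 0.0278; KLK5 -5.70 and -3.93). Luminal markers fell in 10 and rose in 2 of 14 (10 and 2 adjusted over the list alone; adjusted p 0.0179; AGR2 -3.76 and -1.34). For hypoxia and glycolysis 14 genes fell and 2 rose of 25 (14 and 2 adjusted over the list alone; adjusted p 0.0224; VEGFA -2.10 and -0.99), and NRF2 targets fell in 12 of 14 (12 adjusted over the list alone; adjusted p 0.00116; AKR1C2 -7.46 and -4.29). With wild type as the control the luminal list was called (adjusted p 0.00362), and G1/S (0.854), G2/M (0.488), homologous recombination (0.672), keratinocyte (0.145), hypoxia (0.701) and NRF2 genes (0.0704) were not, with the G1/S median turned to -0.058. In both CHEK1 lines 5644 genes differed from shControl, 2780 higher and 2864 lower, with the 3979 genes shared by ATM, ATR, CHEK1 and CHEK2 among them.

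In both lines directed against CHEK2, FST was 178-fold and 64.4-fold higher than in shControl (log2 7.47 and 6.01 ± 0.086, n = 3 arrays per group), LPAR1 17.7-fold and 19.4-fold, and HAS3 15.9-fold and 14.9-fold. IL1B was 26.3-fold and 14.73-fold higher, ARTN 23.9-fold and 12.4-fold, and KRT6C 22.4-fold and 11.1-fold (adjusted p 5.52e-26 and 2.93e-23 for KRT6C). S100A4 was 80.8-fold and 140-fold lower, SERPINA3 50.3-fold and 74.9-fold, and S100P 31.6-fold and 218-fold. Lower too were S100A7 30.9-fold and 183-fold, ABCC3 38.5-fold and 27.9-fold, and CYP1B1 (log2 -4.94 and -5.78). All 6 hairpin arrays lay on one side of the 3 shControl arrays for each of these genes, a condition of the naming rule. RARRES1 was at least 441-fold lower and CCND2 at least 200-fold higher, and CDKN2B was above background on all 6 arrays and on no shControl array. In this pair the library labelled shCHK2-2 held CHEK2 mRNA at 93.2% of shControl. Whatever set all the kinase lines apart from shControl in CDKN2B was not separated from an effect of the CHEK2 hairpins.

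G2/M genes rose in 24 of 32 cases in both CHEK2 lines (24 adjusted over the list alone; adjusted p 0.00363; AURKA 1.53 and 1.43). Among G1/S genes, 13 rose and 1 fell of 29 (13 and 1 adjusted over the list alone; adjusted p 0.00104; CDC25A 1.33 and 1.32). Homologous recombination genes rose in 10 of 24 (10 adjusted over the list alone; adjusted p 0.0343; EXO1 1.07 and 1.14). Fanconi anaemia genes rose in 7 and fell in 1 of 12 (7 and 1 adjusted over the list alone; adjusted p 0.0456; FANCE 0.65 and 1.55). Genes of class I antigen presentation fell in 7 of 12 (7 adjusted over the list alone; adjusted p 0.0284), with HLA-B at -1.63 and -2.32 and TAPBP, a chaperone of peptide loading, at -0.55 and -1.55. Luminal markers fell in 8 and rose in 2 of 14 (8 and 2 adjusted over the list alone; adjusted p 0.0201; ELF3 -2.24 and -2.85). Hypoxia genes and those of glycolysis fell in 14 and rose in 3 of 25 (15 and 3 adjusted over the list alone; adjusted p 0.0343; VEGFA -1.48 and -1.70), and NRF2 targets fell in 14 of 14 (14 adjusted over the list alone; adjusted p 0.00104; AKR1C2 -4.63 and -7.42). Against wild type the luminal list was called (adjusted p 0.00362), and G1/S (0.824), G2/M (0.516), homologous recombination (0.761), Fanconi (0.491), class I (0.0674), hypoxia (0.864) and NRF2 genes (0.059) were not, and the G1/S median turned to -0.033. In both CHEK2 lines 5312 genes differed from shControl, 2540 higher and 2772 lower, with the 3979 genes shared by ATM, ATR, CHEK1 and CHEK2 among them.

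Inflammatory transcripts fell in both sh53BP1 lines against shControl. S100A8 and S100A9, the subunits of calprotectin, were 141-fold and 102-fold, and 29.5-fold and 24.8-fold lower in sh53BP1-1 and sh53BP1-2 (S100A8 log2 -7.13 and -6.67 ± 0.136, n = 3 arrays per group, adjusted p 1.43e-26 and 1.13e-25). The chemokines CXCL8 (92.0-fold and 71.6-fold) and CXCL1 (43.6-fold and 27.9-fold), the cytokine IL1A (37.5-fold and 30.2-fold) and the retinal reductase DHRS3 (24.9-fold and 27.2-fold) were lower. IL6 and PTGS2, below background in the lines, were at least 56.5-fold and 52.8-fold lower. KLK7 was 25.5-fold and 29.9-fold higher, the keratins KRT14 and KRT6C 20.8-fold and 12.8-fold, and 15.9-fold and 14.6-fold, and FKBP5, a chaperone partner of the glucocorticoid receptor, 9.55-fold and 8.52-fold. Also higher were KRT16P2 10.98-fold and 8.06-fold, and DLK2 7.39-fold and 8.09-fold. The 6 hairpin arrays lay on one side of the 3 shControl arrays for each gene given a fold for both lines, as the naming rule required. MTAP and CDKN2A were below background here as in shControl. Of the lower genes, IL6, PTGS2, CXCL1 and S100A8 were also among the largest increases, and KLK7 the largest decrease, in shControl against wild type.

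Inflammatory and secretory factors fell in 17 of 21 cases in both sh53BP1 lines (17 adjusted over the list alone; list test adjusted p 1.32e-05). G1/S genes rose in 25 and fell in 1 of 29 (25 and 1 adjusted over the list alone; adjusted p 1.46e-05), with GMNN, the licensing inhibitor geminin, at 1.31 and 1.31 and GINS2 at 1.17 and 1.08. G2/M genes rose in 25 and fell in 1 of 32 (25 and 1 adjusted over the list alone; adjusted p 0.00113; PLK1 1.73 and 1.48). In these lines homologous recombination genes rose in 15 of 24 (15 adjusted over the list alone; adjusted p 0.00459; EXO1 1.24 and 1.25). Class I antigen presentation genes fell in 9 of 12 (9 adjusted over the list alone; adjusted p 0.00104; HLA-B -3.05 in sh53BP1-1). Mesenchymal and fibroblast markers fell in 10 and rose in 2 of 16 (10 and 2 adjusted over the list alone; adjusted p 0.00544; VIM -3.72 and -3.87). Hypoxia and glycolysis genes fell in 18 of 25 (19 adjusted over the list alone, with 1 that rose; adjusted p 0.000696; NDRG1 -2.72 and -2.02), and NRF2 targets fell in 14 of 14 (14 adjusted over the list alone; adjusted p 0.000696; NQO1 -2.31 and -2.34). With wild type as the control the class I (adjusted p 0.000364) and NRF2 lists (0.0323) were called, and G1/S (0.0674), G2/M (0.565), homologous recombination (0.505), inflammatory (0.0913), mesenchymal (0.368) and hypoxia genes (0.0674) were not. In both TP53BP1 lines 5423 genes differed from shControl, 2657 higher and 2766 lower.

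**Figure D4:**
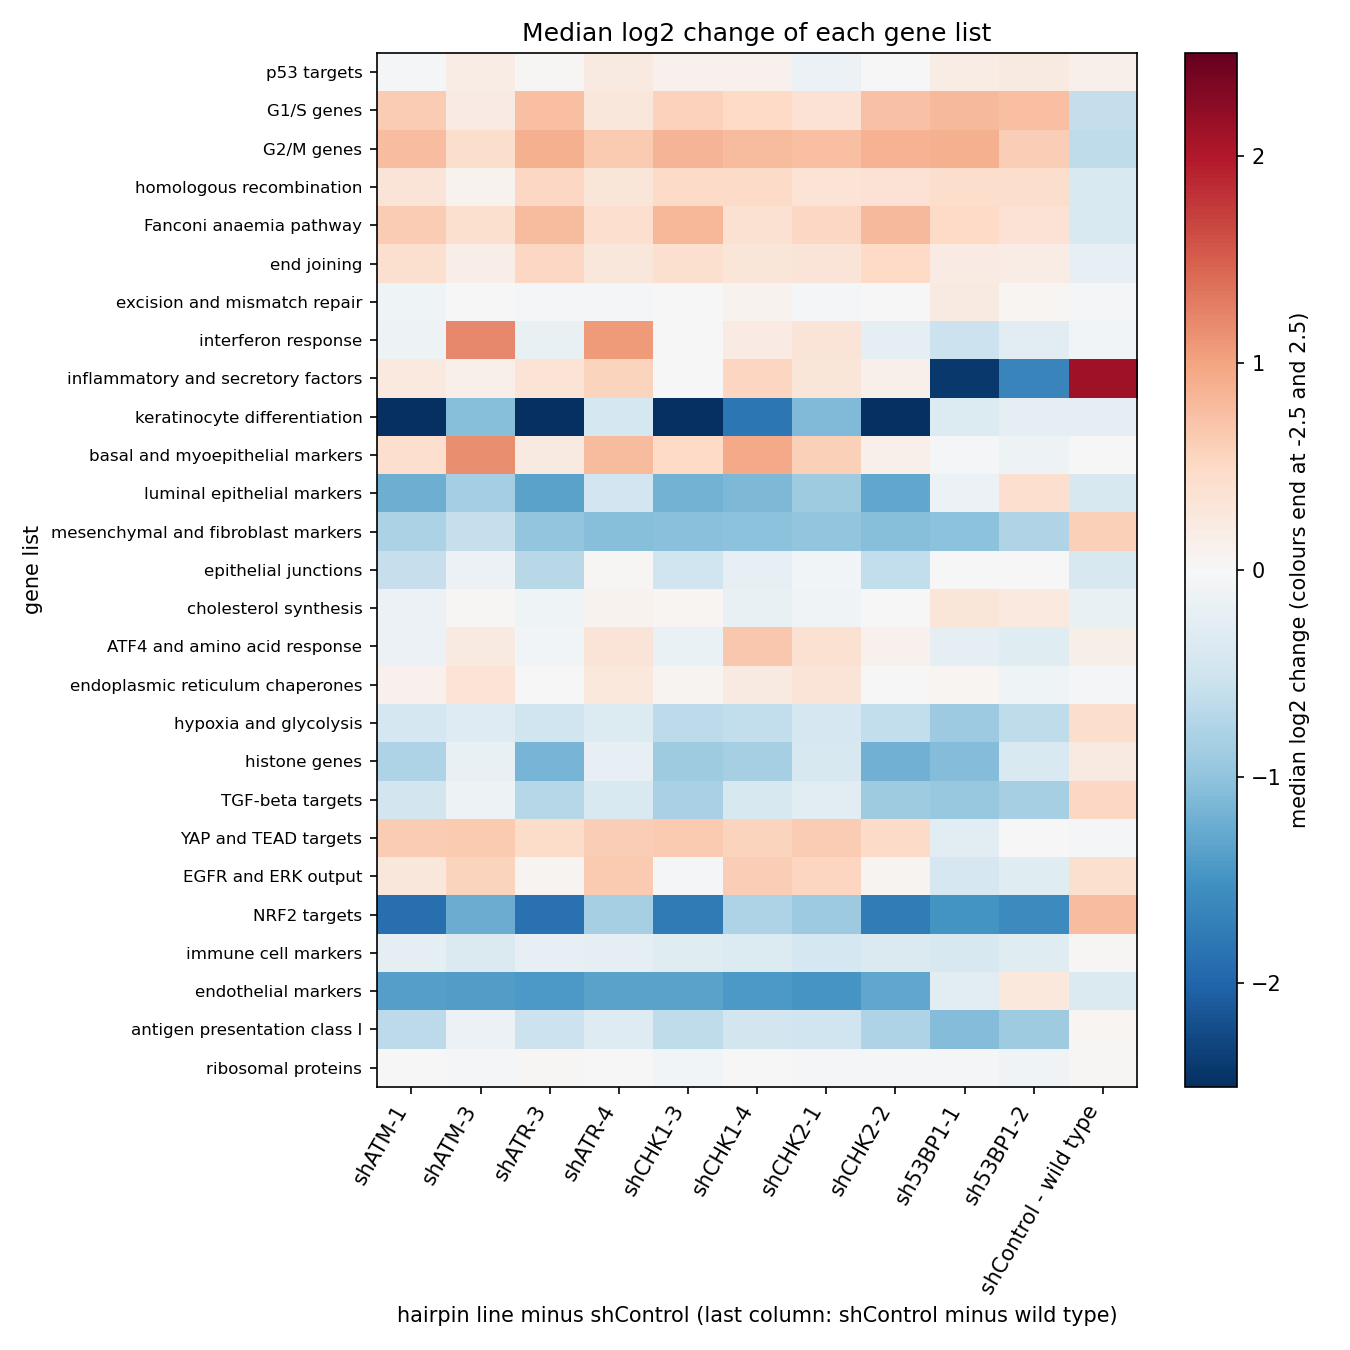
Median log2 change of each of the 27 gene lists (vertical axis) in each of the 10 hairpin lines against shControl, and in shControl against wild type in the last column (horizontal axis). Red marks a higher and blue a lower median, and colours end at -2.5 and 2.5. The G1/S and G2/M medians of shControl against wild type were -0.60 and -0.63.

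Since both hairpins of a target were compared with the same 3 shControl arrays, the counts were set beside chance. In 20 draws of simulated values without any group difference, shControl included, 0 genes were called for each target. These draws held the noise of shared control arrays but no real difference of shControl from the other groups. They therefore do not measure what such a difference adds to the counts. Independent lists of the sizes seen would share 1132 genes up and 1016 down for ATM, 1169 and 1071 for ATR, 1187 and 1129 for CHEK1, 1175 and 1178 for CHEK2, and 895 and 959 for TP53BP1. The 3 control arrays cannot be split into parts of 2 or more, so part of the excess may come from the shared controls. Changes that the kinase lines shared whatever their target also count in it. Of the 4998 ATM genes, 3979 were called with the same sign for ATR, CHEK1 and CHEK2. The excess is therefore not a measure of agreement between the hairpins of 1 target. With wild type in place of shControl, 3496 of the 4998 ATM genes were called with the same sign, and so were 3755 of 5266 for ATR, 4150 of 5644 for CHEK1, 3907 of 5312 for CHEK2 and 3310 of 5423 for TP53BP1. For the kinases this does not remove the shared changes, since MTAP and CDKN2A were below background in wild type as in shControl.

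Genes that differed from shControl in all 10 lines were sought to see what the lines had in common. The keratin gene KRT6C rose by 3.48 to 4.69 on the log2 scale, the notch ligand relative DLK2 by 2.80 to 4.43, and KRT14 by 2.05 to 5.78. The cytokine signalling inhibitor SOCS2 rose by 1.97 to 2.95, the growth factor carrier FGFBP1 by 1.83 to 3.01 and the metallothionein MT1G by 1.79 to 3.73 (30 hairpin against 3 shControl arrays). SFTA1P, RGS2 and PLAGL1 were above background on all 30 hairpin arrays and on 1, 2 and 1 of 3 shControl arrays, and ST6GALNAC5 on 30 and 0 of 3. FABP4, BGN, TNFRSF11B and CYP24A1, which encode a fatty acid carrier, a matrix proteoglycan, osteoprotegerin and the vitamin D hydroxylase, were above background on 3 of 3 shControl arrays and 0 of 30 hairpin arrays. PAPPA, CFB, AKR1B15, AKR1B10, ALDH3A1 and PDZK1IP1 completed the lower genes, with 9, 7, 14, 22, 15 and 1 of 30 arrays above background.

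In all, 2178 genes changed the same way in the 10 lines, 961 up and 1217 down. The simulated draws, where shControl was unchanged too, gave 0, and independent lists would give 0.1 in each direction. Of these, 1157 also differed between shControl and wild type, 1075 of them in the opposite direction, which is 49.4% of the 2178 genes. All 10 named lower genes were higher in shControl than in wild type, and FABP4 and CYP24A1 were above background on no wild type array. Of the named higher genes, MT1G (0.94) was also higher in shControl than in wild type. With wild type as the control 1471 genes changed in all 10 lines, 981 of them shared with the 2178. The smallest change of ST6GALNAC5, KRT14 and RGS2 against wild type was 0.27, 0.16 and 0.26 (largest adjusted p 0.0996, 0.215 and 0.103). Without the sh53BP1 lines, an alternative added after the data were examined, 3979 genes changed in the other 8.

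Each target was also set against the lines of the other 4 targets, which uses no control array. TP53BP1 differed most. MSLN and CYBA, a subunit of the NADPH oxidase, were above background on all 6 sh53BP1 arrays and on 0 of 24 arrays of the other lines, and MUC1 was 109-fold and 114-fold higher in sh53BP1-1 and sh53BP1-2. IL1A was 118-fold and 94.4-fold lower, FST 168-fold and 44.8-fold lower, and CXCL8 31.4-fold and 24.4-fold lower. In these 6352 genes (3192 higher, 3160 lower) the comparator was the 8 lines that stood apart from the 12 other arrays in MTAP and CDKN2A. For ATM 1152 genes were called (681 higher, 471 lower), for ATR 767 (356, 411), for CHEK1 1094 (418, 676) and for CHEK2 1132 (460, 672), with sh53BP1 in the comparator. The genes that led the higher ones for these 4 targets, CCND2, IL1B, DKK3 and TFPI2, were above background on all 24 arrays of the 8 lines and on none of the 6 sh53BP1 arrays. Lower than the mean of the lines of the other targets were MUC1, LCP1 (-1.16 and -1.03) and DBNDD1 in ATM. In ATR they were VGF (-1.21 and -1.32), KHDRBS3 (-1.15 and -1.07) and NME4 (-0.97 and -0.93). For CHEK1 they were S100P, SERPINA3 and KLK5, and for CHEK2 the histone variant MACROH2A2 (-1.71 and -1.84), PHACTR3 and SERPINA3. That mean held the sh53BP1 lines, where MUC1 was high. SERPINA3 was named for both CHEK1 and CHEK2, and DBNDD1 was lower against shControl in both CHEK1 lines than in either ATM line. Such genes were therefore not particular to the target named.

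Against the 6 lines of the other 3 kinases only, a comparison chosen after the data were examined, fewer genes set a target apart: 312 for ATM (230 higher, 82 lower), 42 for ATR (16, 26), 153 for CHEK1 (18, 135) and 155 for CHEK2 (33, 122). By the weaker of the hairpins, the largest decrease was in ATM itself for the ATM lines (-0.71 and -0.85 ± 0.119) and in CHEK1 itself for the CHEK1 lines (-1.37 and -1.39). ATM lines held more of the matrix proteoglycan VCAN (0.87 and 2.21 ± 0.13, n = 3 arrays per line), ZNF358 (0.94 and 0.95), TMEM98 (0.79 and 1.10), and the MYC antagonist MXD4 (1.16 and 0.75). They held less KLHL8 (-0.64 and -0.58), EIF3J (-0.60 and -0.43) and CRKL (-0.61 and -0.42). ATR lines held less SMCO4 (-0.65 and -0.59), EFCAB14 (-0.73 and -0.48) and the thioredoxin inhibitor TXNIP (-0.46 and -0.46). CHEK1 lines held less VCAN (-1.16 and -2.02), S100A7 (-1.12 and -1.10), the lipopolysaccharide receptor CD14 (-0.89 and -0.94), the glucose transporter SLC2A3 (-0.96 and -0.78) and S100A8 (-0.90 and -0.74). They held more FAM167A (1.02 and 0.71). CHEK2 lines held less MACROH2A2 (-1.40 and -1.53), SRGN (-1.39 and -1.13), CHEK2, PHACTR3 (-0.91 and -0.65), FBLN1 (-0.61 and -0.77) and TRIM22 (-0.60 and -0.83). They held more MYLIP (0.78 and 0.73). The lines of each target were part of the comparator of the others, so that VCAN, higher in ATM and lower in CHEK1, counted in both comparisons. More genes were called with opposite signs in the hairpins of a target than with the same sign: 1162 for ATM, 1369 for ATR, 724 for CHEK1 and 1530 for CHEK2.

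In this comparison 18 of 108 pairs of list and target were called on the mean of the hairpins. G2/M genes were lower in ATM (median -0.22, adjusted p 0.000153; mean change against shControl 0.68 in shATM-1 and 0.38 in shATM-3) and higher in CHEK1 (median 0.11, adjusted p 0.00327) and CHEK2 (median 0.09, adjusted p 0.0142). The G2/M mean against shControl was 0.74 in shCHK1-3, 0.80 in shCHK1-4, 0.74 in shCHK2-1 and 0.76 in shCHK2-2. It was as high in shATR-3 (0.76) and lower in shATR-4 (0.56), so the last 2 calls leaned on the low shATM-3 and shATR-4 in the comparator. The ATM call leaned mostly on shATM-3, since the mean in shATM-1 lay above that in shATR-4. Mesenchymal markers were higher in ATM (median 0.24, adjusted p 0.000634). Keratinocyte differentiation genes were lower in CHEK1 (median -0.49, adjusted p 5.39e-05). Their mean against shControl was -2.45 in shCHK1-3 and -1.86 in shCHK1-4, while the comparator held lines with lower means (-2.73 in shATM-1, -2.74 in shATR-3, -2.71 in shCHK2-2) and higher ones. In other calls the hairpins of the pair went opposite ways against shControl. Interferon response genes were called as higher in ATM (adjusted p 2.65e-05) and ATR (0.00238), but their mean change against shControl was -0.19 in shATM-1 and -0.26 in shATR-3, against 1.36 in shATM-3 and 1.09 in shATR-4. They were called as lower in CHEK2 (2.65e-05), with 0.47 in shCHK2-1 and -0.34 in shCHK2-2. They were lower in CHEK1 too (median -0.13, adjusted p 0.000869; -0.011 in shCHK1-3 and 0.29 in shCHK1-4 against shControl), with shATM-3 and shATR-4 in the comparator. Keratinocyte genes, called as higher in ATR (2.04e-06), had a mean of -2.74 in shATR-3 and 0.15 in shATR-4, and inflammatory factors (2.08e-05) -0.16 and 0.84. For p53 targets, called as lower in CHEK2 (0.00125), the means were 0.037 in shCHK2-1 and -0.11 in shCHK2-2.

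The hairpins of a target were compared with each other to see how far sequences against one gene differ. They differed in 4819 genes for ATM, 4528 for ATR, 3576 for CHEK1, 5016 for CHEK2 and 817 for TP53BP1. In the ATM lines the ubiquitin-like modifier ISG15 was 0.45 ± 0.156 against shControl in shATM-1 and 3.91 in shATM-3. The lipocalin LCN2 was -7.01 and -2.35 in the same lines, and the keratin KRT15 -5.68 and -1.47. With only the 6 arrays of the pair in the fit the counts for CHEK1 and TP53BP1 were 1933 and 473.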

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

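The tests of cell origin, array signal, shared response and cell cycle level in this part were chosen after the results were seen, and the counts over other splits of the arrays were planned.

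CHEK2 mRNA differed between the lines directed against it, by -0.89 on the log2 scale (shCHK2-1 minus shCHK2-2, adjusted p 0.000359), in a test of the difference itself. Between targets, the number of the 27 lists whose shift differed was 7 for ATM and ATR, 6 for ATM and CHEK1, 6 for ATM and CHEK2, 5 for ATM and TP53BP1, 5 for ATR and CHEK1, 6 for ATR and CHEK2, 3 for ATR and TP53BP1, 2 for CHEK1 and CHEK2, 4 for CHEK1 and TP53BP1, and 3 for CHEK2 and TP53BP1. These tests took the spread from replicate arrays within lines and not from the difference between hairpins of a target. Keratinocyte genes, for example, were called between ATM and ATR (-0.546). Their mean against shControl was -2.73 in shATM-1, -0.955 in shATM-3, -2.74 in shATR-3 and 0.15 in shATR-4. Inflammatory and secretory factors differed between TP53BP1 and each other target, by 2.85 for ATM, 3.11 for ATR, 2.85 for CHEK1 and 2.81 for CHEK2. Interferon response genes were higher in ATM than in CHEK1 by 0.45 and than in CHEK2 by 0.52, which came from shATM-3 (mean change against shControl 1.36), since shATM-1 (-0.19) lay below both CHEK1 lines (-0.011 and 0.29) and shCHK2-1 (0.47).

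The 8 lines of ATM, ATR, CHEK1 and CHEK2 stood apart from wild type, shControl and sh53BP1. An effect of array signal or normalization was argued against: of 11048 genes, 88 were detected on every array of the 8 lines and no other, and 98 gave the reverse (ratio 0.898), where detection was called before normalization and a difference in array signal would act in 1 direction. Cells of another origin are a candidate explanation, since all 3 genes looked up for this after the split was seen, MTAP, CDKN2A and CDKN2B, which are known to be deleted in MCF-10A, were above background on all 24 arrays of these lines and on none of the other 12. A shared response to losing a kinase of the damage signal would not bring back deleted genes. The log2 signals on single arrays of the 8 lines ran from 8.98 to 10.43 for MTAP, 8.72 to 9.24 for CDKN2A and 6.26 to 8.17 for CDKN2B. In the other groups they reached at most 5.02, 4.93 and 4.92, which argues against that explanation for these 3 genes. For the other genes it stays open, because the distances of the 8 lines from shControl varied only 1.07-fold and could not be related to the fall in target mRNA. Each line carried 1 hairpin, so changes of these 8 lines against shControl were not separated from a difference in cell origin.

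G1/S and G2/M genes were higher than in shControl for all 5 targets. Against wild type, 0 of the 10 pairs of list and target passed upwards, and 3 of 10 medians were above 0.1. Higher cell cycle expression in all hairpin lines would raise most medians against wild type as well, and only 3 were above 0.1. For the ATM, ATR, CHEK1 and CHEK2 lines this count cannot decide, since wild type also differed from them in MTAP, CDKN2A and CDKN2B. For sh53BP1 the pooled count cannot decide either. The G1/S mean against shControl was 0.777 in sh53BP1-1 and 0.708 in sh53BP1-2, and that of shControl against wild type was -0.579. A rise of G1/S genes above wild type in the sh53BP1 lines therefore stays open. A low level of these genes in the shControl arrays may account for the pattern, given the 0 pairs above and the fall of 30 of 32 G2/M genes in shControl against wild type. No further biological explanation was tested.

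For the genes called for both hairpins of each target, only the real split among 100 gave as many. The other splits mixed arrays of different lines, so the test showed that the lines differ. It could not tell whether the hairpins of a target agree beyond chance. The real count and the highest of the other splits were 4817 and 3941 for ATM, 5229 and 4397 for ATR, 5010 and 4550 for CHEK1, 5167 and 1701 for CHEK2, and 5378 and 5187 for TP53BP1. The high counts came from splits that kept the 3 shControl arrays together: among the others the highest were 986 for ATM, 947 for ATR, 141 for CHEK1 and 10 for TP53BP1. No drawn split did so for CHEK2. For genes that set a target apart, splits mixed arrays of different lines, so they tested whether lines differ and not whether the hairpins of a target agree (1 of 100 splits as large, the real one): 1127 for ATM, 752 for ATR, 1066 for CHEK1, 1134 for CHEK2 and 6313 for TP53BP1, against 0 in the others. The splits were of the same kind for genes that differed in all 10 lines, with a real count of 2160 and 0 in the highest other (1 of 100). Splits were too few for the hairpins of one target and for shControl against wild type (1 of 10): 4457 for ATM, 4565 for ATR, 1933 for CHEK1, 4666 for CHEK2, 473 for TP53BP1 and 2935 for the controls, with 0 the highest other in each.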

How the results depend on the processing

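The alternatives without the sh53BP1 lines and with wild type as the control for the target mRNA were chosen after seeing the data. No called mRNA change or named gene reversed in these settings. Named genes as a set were not refitted against wild type. Only the target mRNA and some genes of the comparison of all 10 lines were read there, and ST6GALNAC5, KRT14 and RGS2 lost their call. Genes called with the opposite sign there numbered 43 for ATM, 36 for ATR, 50 for CHEK1, 39 for CHEK2 and 56 for TP53BP1. The deposited log2 values kept the direction and the side of the threshold, or a count within 1.5 times, for 26 of 26 results, as did no background correction, no filter and the replicate block, which gave 34 list calls and 4988 genes for ATM. No background correction gave the deposited values to within 0.0013, so it was not a separate check. The 5 counts with controls not shared between hairpins stayed within 1.5 times, and with a preset correlation 55 list calls were made, which held all 37. Of the named genes, 464 of 470 kept their call with the deposited values and 469 with the block, and 5855 of 5943 with a library left out; the rest lost it. Their size depended on background: with the deposited values 134 of 470 were smaller by over 1.5 times (median ratio 0.767). Wild type as the control gave 13 list calls; a low level in shControl was weighed for the G1/S and G2/M lists only. With only the compared groups in the fit, the comparison between hairpins gave 1933 genes for CHEK1 and 473 for TP53BP1, where fewer arrays estimated the spread. Counting all probes raised counts because more features were tested: 7735 for ATM, 8193 for ATR, 8846 for CHEK1, 8452 for CHEK2 and 8616 for TP53BP1, 3345 for all 10 lines, 10097 for TP53BP1 against other targets, and 7866, 7546, 5987 and 8197 between the hairpins of ATM, ATR, CHEK1 and CHEK2. Without the sh53BP1 lines, genes that set a target apart numbered 312 for ATM, 42 for ATR, 153 for CHEK1 and 155 for CHEK2, and 3979 genes changed in the other 8 lines. For the genes set apart the comparator changed with the lines left out, and the cause was not tested further. In the same setting CHEK2 mRNA in shCHK2-2 was -0.66 against the lines of ATM, ATR and CHEK1, which replaced shControl. With sh53BP1 kept in that comparator it was -0.79, so the move from -0.10 came with replacing shControl. With each library left out in turn, CHEK1 mRNA ran from -0.33 to -0.17 in shCHK1-3 and from -0.34 to -0.19 in shCHK1-4, and no longer passed without shControl replicate 3 (both), shCHK1-3 replicate 1 or 3, or shCHK1-4 replicate 2. List calls ran from 33 to 42, genes changed in all 10 lines from 1978 to 2252, and CHEK2 mRNA in shCHK2-2, which was not called, from -0.35 to 0.16, turning its direction without shControl replicate 3. Between 33.5% and 38.3% of probes were above background, which left ATR mRNA unread. The slide as a block was not run, since no slides were given.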

Other observations

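The tests in this part were planned, and GSTM1 and GSTT1 were chosen after their values were seen. Lists that were called for no target are given here as the numbers of genes that rose and fell in both hairpins against shControl, in the order ATM, ATR, CHEK1, CHEK2 and TP53BP1. Example genes are from the ATM lines. Of 27 measured p53 targets the numbers were 8 and 5, 9 and 6, 11 and 6, 6 and 7, 8 and 7, with GDF15, a stress cytokine, at -3.72 and -1.82 and the growth arrest gene GADD45A at 2.49 and 2.91. Of 11 end joining genes they were 3 and 0, 4 and 1, 3 and 0, 3 and 0, 3 and 0, and of 26 excision and mismatch repair genes 4 and 3, 3 and 3, 3 and 3, 5 and 3, 6 and 1, with NEIL2 at -0.86 and -0.94. Basal and myoepithelial markers (12 measured) gave 7 and 1, 5 and 1, 7 and 1, 5 and 1, 2 and 3, with KRT14 at 2.27 and 4.94 and KRT15 at -5.68 and -1.47. Epithelial junction genes (20) gave 5 and 7, 4 and 5, 5 and 9, 4 and 9, 3 and 4, with CLDN1 at -3.57 and -2.07.

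TGF-beta targets (16 measured) gave 5 and 5, 5 and 8, 5 and 9, 6 and 8, 1 and 10. The adjusted p was 0.0602 for TP53BP1 and 0.665 for ATM, and THBS1 was 2.29 and 2.60. YAP and TEAD targets (18) gave 10 and 1, 10 and 1, 10 and 1, 10 and 1, 3 and 7, with AXL at 2.88 and 2.30 (adjusted p 0.053 for ATM and 0.632 for TP53BP1). EGFR and ERK output genes (19) gave 7 and 2, 6 and 3, 6 and 2, 6 and 2, 4 and 8, with DUSP5 at 1.91 and 1.06. Cholesterol synthesis genes (20) gave 5 and 3, 5 and 4, 6 and 5, 5 and 4, 8 and 3, with INSIG1 at -1.33 and -1.26, ATF4 and amino acid response genes (18) 6 and 5, 6 and 5, 7 and 5, 7 and 5, 4 and 9, and endoplasmic reticulum chaperones (14) 4 and 2, 5 and 2, 3 and 2, 4 and 2, 3 and 4. Histone genes (12) gave 1 and 6, 1 and 4, 2 and 7, 2 and 7, 2 and 6, with H1-2 at -1.88 and -1.61, and ribosomal protein genes (26) 2 and 5, 2 and 6, 2 and 5, 3 and 3, 3 and 4, with RPS23 at 2.84 and 2.46. Immune cell markers (6) gave 0 and 3, 0 and 2, 0 and 3, 0 and 2, 1 and 1, and endothelial markers (3) 1 and 2, 1 and 2, 1 and 2, 1 and 2, 0 and 1. Against wild type, inflammatory and secretory factors rose for ATM (median 2.42, adjusted p 0.00028), ATR (2.46, 0.000128), CHEK1 (1.72, 0.000364) and CHEK2 (2.20, 0.000411), and EGFR and ERK output genes rose for ATM (0.76, 0.0445) and CHEK1 (0.66, 0.0445). The scrambled control also lay above wild type, with medians of 2.12 for the inflammatory list and 0.39 for EGFR and ERK output genes. Neither list was called for these targets against shControl, and the kinase lines also differed from wild type in MTAP and CDKN2A.

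GSTM1, a glutathione transferase often absent from human genomes, was above background on 4 of 12 arrays of wild type, shControl and sh53BP1 and on 0 of 24 of the other lines, and GSTT1 on 0 of 12 and 24 of 24. The number of genes above background in both lines of a target and on no shControl array ran from 34 for TP53BP1 to 182 for ATM, and the reverse held for 302 genes for TP53BP1 to 451 for CHEK2.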
